A study of Mus musculus with 6 samples.

How the data were processed

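Total RNA from cultured mouse cells was labelled with biotin and hybridised to Affymetrix arrays, from 1 to 8 ug of RNA, per the labels' protocols. The mice were C57BL/6N animals of 15 to 16 weeks. Macrophages positive and negative for Ccrl2 were sorted from 6 pooled hearts 1 week after TAC, and cardiac fibroblasts or cardiomyocytes were kept with PBS or with a macrophage secretome for 48 h. The labels' protocols speak of co-culture with macrophages while the source labels name the secretome, and a sample description speaks of cardiac macrophages, although the protocols say that fibroblasts and cardiomyocytes were profiled. The source labels were followed for the groups. There were 6 groups of 1 array each, so no spread between samples could be estimated.

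The deposited values are log2 probe set summaries made with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summary algorithm, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The log2 scale was read from the deposited values. The sorted values of the arrays nearly coincide, with a mean gap of 0.03 and a largest gap of 0.168, so the arrays had been brought to almost one distribution before deposit. Such a step removes any difference in the overall level between arrays, and a change of most genes in one direction would not be seen. The values were not centred per gene, and no scanner files were used here.

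The table held 28846 probe sets. The platform's probe annotation gave 1 symbol for 19572 of them, several for 0 and none for 9274, of which 5222 were negative controls, 1324 other control probe sets, 63 ERCC controls, 23 antigenomic background, 8 spike-in and 2634 other probe sets unnamed here. All 19572 Entrez identifiers matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. For 55 symbols with several probe sets, the probe set with the highest mean over the arrays was used, leaving 19505 genes.

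For each comparison the log2 values of a pair of arrays were subtracted. A gene was counted when the higher of its values reached the floor of 6.55, the median of all named values, and its difference reached 2-fold. Where the lower value lay below the floor, the difference between the higher value and the floor is printed as a lower bound. No p-value was computed. For 41 gene lists fixed beforehand, of which 40 had at least 1 gene on the array, the median difference of members past the floor was placed among 10000 random lists of equal size matched on mean expression in 20 bins. A list stood apart when it lay outside the central 95%, as a description of these arrays, and lists with fewer than 5 such members got no percentile. Of the 194 pairs of list and secretome comparison ranked, 51 lay above and 57 below. Lists share some members.

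Genes named in the text were chosen by a rule: the 10 largest differences per direction, of which fewer may stand in the text, without predicted, olfactory, vomeronasal, microRNA, small nucleolar and clone symbols; up to 4 members per list with the largest difference or, for lists not apart, nearest 0; Ccrl2 and marker genes of macrophages, fibroblasts and cardiomyocytes; and genes at 2-fold in both cell types between the secretomes. Lists, rule, groups, comparisons and all alternatives but 1 were fixed before the data were examined. Genes named outside the rule are marked.

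Comparisons that share a PBS array share its chance values. The correlation and covariance expected from that were simulated in 100 sets of unchanged arrays. The alternatives were thresholds of 1.5- and 3-fold, no floor, a floor at the 75th percentile (10.14), quantile normalization on top, a loess trend with a span of 0.4 removed, the mean of a gene's probe sets, Spearman's rho and random lists without matching. Raising values below the floor to it was added after the data were seen.

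The counting step was tested on simulated data for the Ccrl2+ over PBS comparison in CF with 19505 genes. It recovered 98% of 50 genes changed by 1.5 log2 units in each direction and 100% changed by 3, and it called 0.06% of unchanged genes. The simulated noise came from the difference between the cardiomyocyte secretome arrays, the closest pair, and only genes well above the floor were changed. These rates can therefore be too favourable for CF. On the real arrays of this comparison 19.7% of negative control probe sets past the floor differed by at least 2-fold. Of 200 unchanged lists 5% stood apart, and of 200 lists shifted by 0.5 all did. The simulated lists were drawn from genes with independent noise, so the 5% does not cover lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.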

Results

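Gene expression was measured on 6 Affymetrix arrays of mouse heart cells in culture. Cardiac fibroblasts (CF), the matrix-producing cells of the heart, and cardiomyocytes (CM), its contractile cells, were each kept for 48 h with phosphate-buffered saline (PBS), with the secretome of Ccrl2+ macrophages or with the secretome of Ccrl2- macrophages. The sample titles call the PBS arrays sham. Ccrl2 encodes a chemokine-receptor-like protein that binds chemerin without known signalling of its own. The macrophages had been sorted from 6 pooled wild-type hearts 1 week after transverse aortic constriction (TAC), a surgical pressure overload of the left ventricle. The comparisons ask what factors from each macrophage population do to fibroblasts and to cardiomyocytes. Each of the 6 groups had 1 array, so no difference has a replicate check, no test was made, and the number of arrays limits the precision throughout.

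Values are log2 probe set summaries, and a difference of 1 is 2-fold. The median over named probe sets lay between 6.5 and 6.59 on the 6 arrays. Across genes, which are not independent replicates, the lowest Pearson correlation between any pair of CM arrays was 0.995. Pairs of CF arrays gave 0.973 to 0.986, and CF against CM pairs gave 0.937 to 0.953. The floor for counting a gene was the median of named values, 6.55, and the median of the negative control probe sets on the 6 arrays lay between 6.2 and 6.71, so values near the floor are close to background. Where the dimmer value of a pair lay below the floor, the difference is given as a lower bound against the floor. Genes with near-identical copies, such as Serpina3f, Serpina3n, Saa3, Ifit1, Ifit3, Ifit3b and the H2 genes, are uncertain because their probes can bind related transcripts.

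The PBS arrays carried the marker genes of the cell types in their labels. In CF over CM, 1449 of 10394 genes past the floor were at least 2-fold higher and 1756 at least 2-fold lower. Of the negative control probe sets 747 were at least 2-fold higher and 141 lower, 30.6% of those past the floor against 30.8% of genes, with a median of 0.55. The matrix glycoprotein gene Mfap4 (16.94 against 6.55), the secreted Wnt modulator Sfrp2 (15.69 against 6.73) and Col3a1 (17.4 against 8.78) were higher in fibroblasts. Tcf21, a transcription factor of cardiac fibroblasts, was at least 8.45 higher (15.0 against 6.2), and Fmod at least 7.25 higher (13.8 against 3.96). Of 16 fibroblast identity genes past the floor, 14 were at least 2-fold higher in CF, with a median of 2.9. All 22 sarcomere genes past the floor were at least 2-fold lower in CF, with a median of -7.52 (-6.96 with values below the floor raised to it), among them Myoz2 (7.34 against 16.54) and Tnni3 (6.92 against 15.92). Bmp10, Lrrc10 and the calcium release channel gene Ryr2 were lower in CF by at least 8.57, 7.42 and 7.18. All 32 oxidative phosphorylation genes past the floor were at least 2-fold lower in CF (median -2.25), led by Cox6a2 (7.58 against 16.91). The TCA cycle (-2.34) and fatty acid oxidation (-1.58) medians were lower as well. Endothelial markers were lower in CF, with a median of -4.43 and 15 of 16 genes at least 2-fold lower, for example Kdr (6.59 against 12.74) and Pecam1 (8.31 against 13.87), so the CM array carried endothelial transcripts. The fibroblast marker Dcn was also high in CM, at 15.34 against 17.53 in CF, while Col1a1 lay at 10.13 against 16.63. Which cells of the cardiomyocyte culture carried Dcn was not tested. Epicardial and mesothelial markers were higher in CF (median 2.28), as in Upk3b (14.04 against 9.39). Both PBS arrays carried leukocyte transcripts, with Ptprc at 9.06 in CF and 8.86 in CM and the lysozyme gene Lyz2 at 12.52 and 12.88, and the macrophage marker median did not stand apart (-0.01). Among cardiomyocyte markers, Tnnt2 lay at 16.12 in CF against 18.03 in CM, and Myh6 at 9.63 against 17.32. The Myh6 value in CF lay below 10.74, the 95th percentile of the negative controls on that array. Which cells of the fibroblast culture carried Tnnt2 was not tested. Lcn2, which encodes an iron-siderophore-binding acute phase protein, lay at 15.76 in CM and 3.85 in CF, at least 9.21 lower.

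The fibroblast culture of the array labelled Ccrl2- secretome carried far higher levels of inflammatory and acute phase genes than the fibroblast culture in PBS. Which cells of the culture carried these transcripts was not tested. Lcn2 was at least 10.73 higher (17.28 against 3.85). The neutrophil chemokine genes Cxcl5 (16.56 against 4.86), Cxcl2 (14.95 against 4.12) and Cxcl1 (14.52 against 4.52) were higher by at least 10.01, 8.4 and 7.97. Sele, the adhesion molecule E-selectin, was at least 9.29 higher, Clec4e, a pattern recognition receptor, at least 8.92, and Acod1, the enzyme that makes itaconate, at least 6.88. The acute phase gene Saa3 (17.88 against 8.77), Serpina3f (15.42 against 6.66) and the interferon-induced chemokine gene Cxcl10 (13.47 against 4.57, at least 6.92 higher) were higher as well.

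By gene list, 20 of 22 cytokine and chemokine genes past the floor were at least 2-fold higher and 0 lower, with a median of 5.12, above the central 95% of expression-matched random lists (-0.28 to 0.35). All 20 genes of the NF-kB feedback and acute phase list were at least 2-fold higher (median 4.38), including the pentraxin gene Ptx3 (14.65 against 6.53, at least 8.1) and the prostaglandin E synthase gene Ptges (13.28 against 5.49, at least 6.73). Of 20 interferon-stimulated genes, 18 were at least 2-fold higher (median 3.52), such as Oasl2 (13.41 against 8.52), Usp18 (11.45 against 7.07) and Ifit1 (11.83 against 5.71, at least 5.28). Of 19 antigen presentation and interferon-gamma response genes, 18 were higher (median 3.2), led by the guanylate-binding protein genes Gbp2 (15.1 against 7.44) and Gbp3 (13.69 against 7.95). With values below the floor raised to it, an alternative chosen after the data were seen, these medians were 4.38, 4.08, 3.16 and 3.12. The complement median did not stand apart (0.24), but Cfb was at least 4.69 higher and C1s1 reached 11.72 against 8.15. Of 21 macrophage markers past the floor, 5 were at least 2-fold higher and 8 lower. Their median was -0.45, below the random range, with Cybb (14.77 against 11.13) and Cd14 (11.3 against 8.54) higher and the complement component genes C1qa (9.42 against 11.22) and C1qc (8.11 against 9.84) lower.

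Genes of glycolysis and the hypoxia response were also higher in this array, 21 of 24 by at least 2-fold and 0 lower, with a median of 2.04. Examples were the lactate exporter gene Slc16a3 (14.12 against 8.89), the mitophagy gene Bnip3 (12.63 against 8.19), the prolyl hydroxylase gene Egln3 (15.45 against 11.22) and the phosphofructokinase gene Pfkl (13.64 against 9.83). Immediate early genes (median 0.89, 9 of 20 at least 2-fold higher), among them Ier3 (15.23 against 10.74) and Junb (10.44 against 7.1), lay above the random range. So did oxidative stress and metallothionein genes (0.53), with Mt2 at 17.85 against 14.63 and the cystine transporter gene Slc7a11 at 11.98 against 9.42. The cell death (0.46), p53 target (0.21) and unfolded protein response (0.16) medians were above it too, with Casp4 (13.54 against 10.38), Mlkl (13.5 against 10.7) and Fas (11.0 against 8.46) among the largest members. Of the matrix protease list, Mmp3 (17.08 against 8.57), Mmp12 (14.48 against 6.96) and the inhibitor gene Timp1 (15.28 against 12.03) were higher, while the list median was -0.04.

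Contractile and fibroblast identity genes were lower. The myofibroblast contractile median was -0.86 with 5 of 14 genes at least 2-fold lower, such as Cnn1 (7.59 against 9.49), Mylk (11.15 against 12.86) and Actg2 (7.96 against 9.56). Fibroblast identity genes had a median of -0.62, with Gsn (12.87 against 14.5) and Cd248 (9.95 against 11.47) lower and 0 genes at least 2-fold higher. The fibroblast activation and TGF-beta response median was -0.51, with Tgfb3 (12.6 against 14.24) and Pmepa1 (12.27 against 13.84) lower, although Timp1, a member, was higher. The collagen and matrix median did not stand apart (-0.18), and Col1a1 lay at 16.45 against 16.63. The largest lower values were those of the growth factor genes Bmp3 (8.29 against 11.47) and Fgf18 (8.02 against 10.79), the purinergic receptor gene P2ry12 (6.63 against 9.03), Sytl2 (10.28 against 12.65) and Pcdh18 (9.64 against 11.91). Chondrogenic and osteogenic (-0.83) and epicardial (-0.59) medians were lower, although the retinaldehyde dehydrogenase gene Aldh1a2 of the latter list was higher (14.65 against 11.93). With values below the floor raised to it the epicardial median was -0.35, inside its random range of -0.39 to 0.22. Mitosis (-0.1), DNA replication (0.03), sarcomere (-0.29) and oxidative phosphorylation (-0.12) medians lay within the random range. Ccrl2 itself was at least 4.82 higher in this array (11.37 against 6.5), which describes the fibroblast culture and not the sorted macrophages. In total 622 of 10057 genes past the floor were at least 2-fold higher and 486 lower. Of the negative control probe sets past the floor, 13.1% also differed by at least 2-fold, with extremes of -8.79 and 6.03. Among values of at least 10.51, the 95th percentile of the controls, 12.1% of genes and 17.8% of controls differed by as much.

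The fibroblast culture of the array labelled Ccrl2+ secretome differed from PBS in other genes. Serpina3n, a serine protease inhibitor gene of the acute phase, was 179.8-fold higher (16.37 against 8.88). The transcription factor gene Zbtb16 was at least 6.89 higher (13.44 against 6.35). The flavin monooxygenase genes Fmo2 (14.93 against 8.64) and Fmo1 (13.07 against 7.42), the amino acid transporter gene Slc38a5 (16.5 against 10.47), Art3 (13.68 against 7.99), the glucocorticoid receptor co-chaperone gene Fkbp5 (15.15 against 10.24) and the angiotensin-converting enzyme gene Ace (13.8 against 9.01) followed. Lcn2 was at least 4.41 higher (10.96 against 3.85). Lower than in PBS were the melatonin receptor gene Mtnr1a (4.64 against 9.41, at least 2.86 lower), the activated fibroblast gene Cthrc1 (7.17 against 10.98), Map3k7cl (at least 2.88 lower), the aryl hydrocarbon receptor gene Ahr (5.92 against 9.3, at least 2.75) and Kif26b (7.44 against 10.6).

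Cell division genes were lower as a group. All 23 mitosis genes past the floor were at least 2-fold lower, with a median of -1.96, for example Ccna2 (8.83 against 11.72), Prc1 (7.26 against 9.98) and Kif20a (8.96 against 11.51). Of 24 DNA replication genes 18 were at least 2-fold lower (median -1.26), such as Rrm2 (9.17 against 11.27) and Prim1 (8.97 against 11.05). Unfolded protein and integrated stress response genes had a median of -0.86, with 11 of 25 at least 2-fold lower, among them Slc7a11 (7.27 against 9.42), Mthfd2 (10.75 against 12.58) and Trib3 (8.65 against 10.08). Cholesterol and lipid synthesis (-0.45), fibroblast activation (-0.33) and growth factor (-0.31) medians also lay below the random range. Examples were Dhcr7 (11.12 against 12.1), Itga11 (6.98 against 9.54) and the neurotrophin gene Bdnf (9.62 against 11.43). The lists of smooth muscle and of neuronal markers had fewer than 5 genes past the floor and no percentile. Their medians were -0.75 and -1.83.

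The NF-kB and acute phase median was higher (0.88), with 4 of 15 genes at least 2-fold higher, including Birc3 (12.71 against 11.19) and Cebpd (12.29 against 10.77). The complement median was 0.88, with C7 (10.05 against 6.99) and C1s1 (10.26 against 8.15), and the antigen presentation median 0.54, with H2-T23 (9.66 against 7.82) and Tap1 (8.29 against 6.97). The cytokine median (0.24) lay within the random range, and 3 of 11 members were at least 2-fold lower, among them Il6 (6.03 against 8.79, at least 2.24). Interferon-stimulated genes did not stand apart (0.09). Sarcomere genes had a median of 0.91, with Myoz2 (9.8 against 7.34), Myh6 (11.13 against 9.63) and Actn2 (10.6 against 9.2) higher and Myl4 lower (11.54 against 13.26). Fatty acid oxidation (0.22), led by the pyruvate dehydrogenase kinase gene Pdk4 (10.51 against 7.19), matrix proteases (0.19) and endothelial markers (0.28), led by Fabp4 (11.41 against 8.05), lay above the random range. The calcium handling median did so too at 0.24, and it was -0.29 with the floor at the 75th percentile. Collagens (0.1), fibroblast identity (-0.05), macrophage markers (0.14), glycolysis (0.05) and oxidative phosphorylation (-0.03) did not stand apart. Ccrl2 lay at 7.03 against 6.5. In total 489 of 10042 genes were at least 2-fold higher and 616 lower, and 19.7% of negative control probe sets past the floor differed by as much. The 4 poly-A spike-in transcripts were higher in this array by a median of 0.605, and the 4 hybridisation spike-in transcripts by 0.305.

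**Figure D1:**
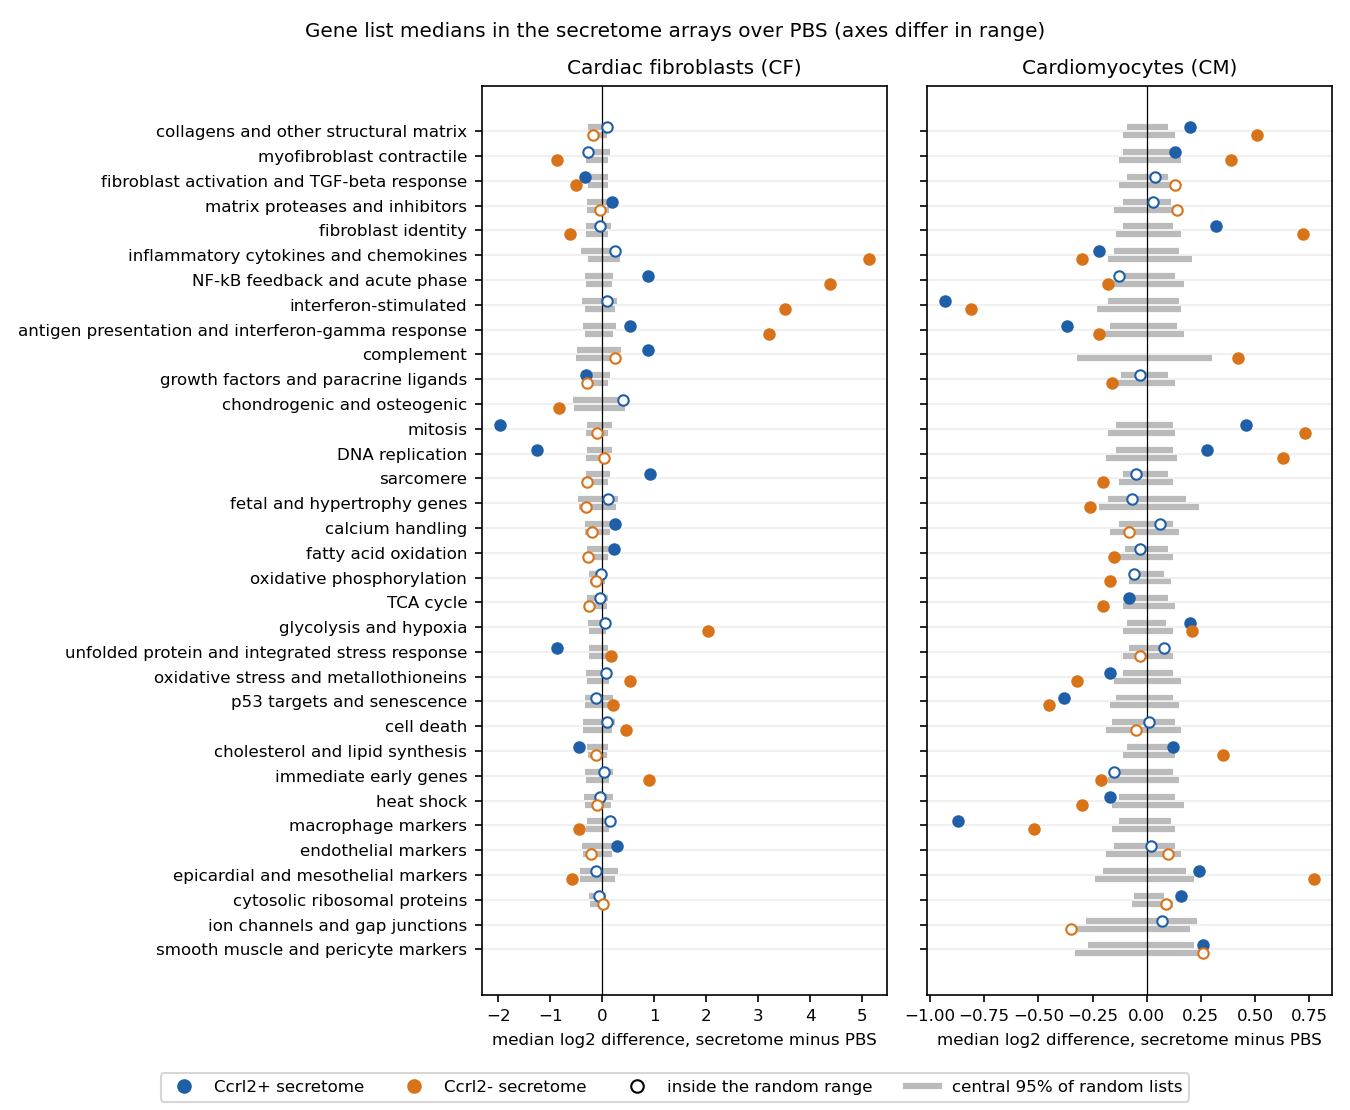
Median log2 difference (secretome array minus PBS array, horizontal axes) of each gene list with at least 5 genes past the floor in cardiac fibroblasts (left) and cardiomyocytes (right, on a narrower scale). Blue points are the Ccrl2+ secretome, orange points the Ccrl2- secretome, grey bars the central 95% of 10000 matched random lists, and open points lie inside that range: the fibroblast cytokine median reached 5.12 in the array labelled Ccrl2- and the mitosis median -1.96 in the array labelled Ccrl2+, while the lowest cardiomyocyte median was -0.93, of interferon-stimulated genes.

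In the direct comparison the fibroblast arrays differed in 1889 of 10144 genes past the floor, 867 at least 2-fold higher and 1022 lower with the Ccrl2+ secretome than with the Ccrl2- secretome. The share of negative control probe sets at 2-fold was 19%. Of 22 cytokine genes 21 were at least 2-fold lower with Ccrl2+ (median -5.69), including Tnf (3.69 against 12.3, at least 5.75 lower). All 20 NF-kB genes (median -4.01), 19 of 20 interferon-stimulated genes (-3.58) and 18 of 19 antigen presentation genes (-2.82) were lower as well. With values below the floor raised to it these 4 medians were -4.51, -3.72, -3.09 and -2.66. Mmp12 (4.51 against 14.48, at least 7.93) and Mmp3 (9.35 against 17.08) were lower, and so were the glycolysis and hypoxia list (-2.04), with Slc16a3 (7.83 against 14.12) and Hk2 (8.06 against 11.71), and mitosis genes (-1.99), with Bub1 at 7.19 against 10.3. The DNA replication median was -1.34. Unfolded protein response (-1.07), cell death (-0.59), oxidative stress (-0.55) and p53 target (-0.51) medians were also lower. Higher with Ccrl2+ were Slc38a5 (16.5 against 8.65), Fmo2 (14.93 against 8.47), the matrix protein gene Sparcl1 (13.31 against 8.02), the serine protease gene Htra3 (11.65 against 7.03) and Cbr2 (11.44 against 6.7). The sarcomere (1.2), chondrogenic (1.07), endothelial (0.62), myofibroblast contractile (0.52), calcium handling (0.48) and fibroblast identity (0.44) medians were above the random range. Examples were Tnnt2 (17.03 against 15.08), Sox9 (13.72 against 10.81), Mylk (12.85 against 11.15) and Gsn (16.47 against 12.87). The 4 poly-A spike-in transcripts were higher with Ccrl2+ by a median of 0.89, and the 4 hybridisation spike-in transcripts by 0.33. The macrophage marker median did not stand apart (0.25), with Cd14 (7.28 against 11.3) and Cybb (10.8 against 14.77) lower and C1qc (11.07 against 8.11) and Mertk (11.67 against 8.91) higher. Collagens (0.11), growth factors (-0.08) and ribosomal protein genes (-0.08) lay within the random range.

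**Figure D2:**
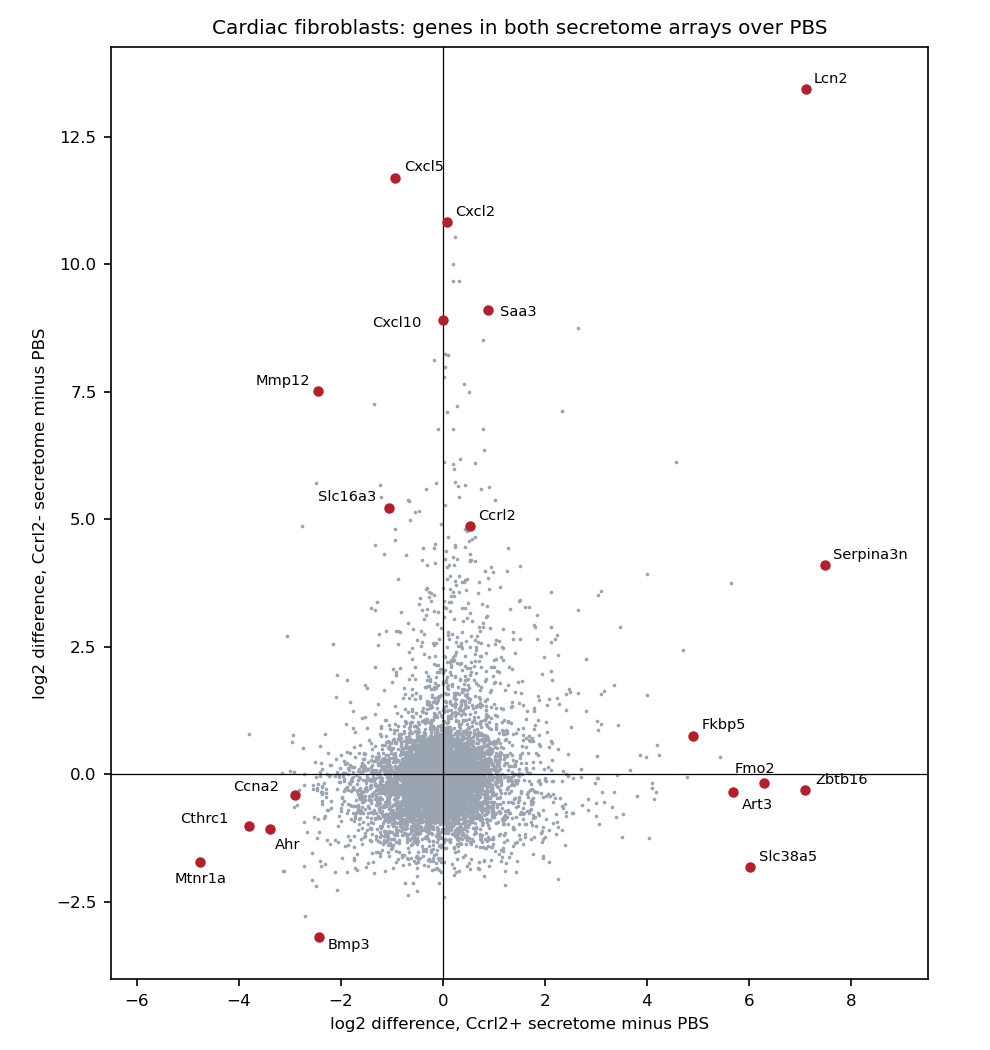
Log2 difference from PBS in cardiac fibroblasts with the Ccrl2+ secretome (horizontal axis) and with the Ccrl2- secretome (vertical axis). Each point is 1 gene past the floor in at least 1 of the 3 arrays, and red points are named: Cxcl5 and Cxcl2 lie high on the vertical axis within 1 of 0 on the horizontal one, Zbtb16, Fmo2 and Fkbp5 lie far right within 1 of 0 on the vertical one, and Lcn2 is high on both.

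The fibroblast differences from PBS overlapped in part. Lcn2 was at least 4.41 and at least 10.73 higher with the Ccrl2+ and the Ccrl2- secretome, and Mt2 lay at 17.27 and 17.85 against 14.63 in PBS. Across 9840 genes, Pearson's r of the log2 differences was 0.188 and the covariance 0.099. Unchanged groups simulated against a shared PBS array gave an r of 0.5 and a covariance of 0.0303. At 2-fold, 98 genes were higher in both, against 20.3 for independent lists, and 102 lower in both, against 30.4. In opposite directions, 50 genes were higher with Ccrl2+ and lower with Ccrl2-, against 20.4, and 27 the reverse, against 30.2. Unchanged groups with a shared PBS array gave 0.34 genes shared in either direction on average over the simulated sets. The noise in that simulation was taken from the difference between the cardiomyocyte secretome arrays, the closest pair, and so can be too low for fibroblasts. The PBS array could not be split.

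Cardiomyocytes differed much less between arrays than fibroblasts. With the Ccrl2+ secretome 21 of 10009 genes past the floor were at least 2-fold higher than in PBS and 63 lower. The leading differences were lower values of chemokine and interferon-induced genes. The macrophage inflammatory protein gene Ccl3 (9.92 against 12.1), the antiviral genes Rsad2 (7.45 against 9.53), Ifit1 (6.62 against 8.58), Ifit3 (9.09 against 10.96) and Ifit3b (8.77 against 10.86), the interferon pathway protease gene Usp18 (6.8 against 8.69) and the receptor gene Tlr7 (10.96 against 12.44) were lower. The interferon-stimulated list had a median of -0.93, below the random range of -0.18 to 0.15, with 7 of 16 genes at least 2-fold lower and 0 higher. The antigen presentation (-0.37) and cytokine (-0.22) medians were also below it. Macrophage markers were lower in the same array, with a median of -0.87 and 8 of 20 genes at least 2-fold lower, such as C1qb (10.9 against 12.25), C1qc (9.39 against 10.69) and the mannose receptor gene Mrc1 (11.76 against 12.92). Ptprc lay at 8.29 against 8.86.

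Smaller differences in list medians were found in other groups of this comparison. Mitosis genes had a median of 0.46 and DNA replication genes 0.28, with 0 members at 2-fold in either direction, and the examples Cdk1 (9.09 against 8.38) and Cdc6 (7.95 against 7.09). Fibroblast identity (0.32) and collagen (0.2) medians were above the random range, with Col3a1 (9.77 against 8.78) and Cd248 (8.88 against 7.98). So were smooth muscle (0.26), epicardial (0.24, but 0.09 and inside the range with values below the floor raised to it), glycolysis (0.2), ribosomal protein (0.16), myofibroblast contractile (0.13) and cholesterol synthesis (0.12) medians, with Slc16a3 (9.85 against 8.6) and Egln3 (12.38 against 11.34) as the largest glycolysis members. The p53 target median was -0.38, led by Eda2r (12.08 against 12.77), and heat shock (-0.17), oxidative stress (-0.17) and TCA cycle (-0.08) medians were below the range. Sarcomere (-0.05), calcium handling (0.06), fatty acid oxidation (-0.03) and fetal gene (-0.07) medians did not stand apart. Myh6 lay at 17.27 against 17.32, and the natriuretic peptide gene Nppb at 15.14 against 15.48. Of the negative control probe sets past the floor 12.9% differed by at least 2-fold, against 0.84% of genes. Among values of at least 10.51 these shares were 19.5% and 0.5%, so the controls scattered more than genes of like level.

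With the Ccrl2- secretome, cardiomyocyte arrays had higher matrix and fibroblast genes than in PBS, and 75 of 10054 genes were at least 2-fold higher and 79 lower. Col3a1 (10.93 against 8.78), Col11a1 (8.89 against 6.89), the fibroblast surface gene Cd248 (9.89 against 7.98), Itgbl1 (10.51 against 8.72) and the complement inhibitor gene Serping1 (11.19 against 9.58) were among the 10 largest, with Fmo2 (10.26 against 8.18) and the centromere gene Cenph (8.79 against 6.69). The fibroblast identity median was 0.72, with 5 of 15 genes at least 2-fold higher, and the collagen median 0.51, with 6 of 22. Thy1 (12.11 against 10.88), Col1a1 (11.3 against 10.13) and Col1a2 (12.28 against 10.91) were examples. Epicardial markers (0.77), including Lrrn4 (11.27 against 9.69), and myofibroblast contractile genes (0.39), including Mylk (8.22 against 6.93), were higher too. The complement median was 0.42 over 5 genes and 0.06 with values below the floor raised to it. Mitosis (0.73) and DNA replication (0.63) medians were above the random range, with Top2a at 9.6 against 8.58, as were cholesterol synthesis (0.35), led by Scd1 (14.51 against 13.69), and glycolysis (0.21).

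Interferon-stimulated genes were lower with this secretome as well, with a median of -0.81 and 6 of 16 genes at least 2-fold lower, such as Rsad2 (6.97 against 9.53), Ifit1 (6.55 against 8.58) and Oasl2 (7.86 against 9.31). The macrophage marker median was -0.52, with 0 genes at 2-fold and Fcgr1 at 8.28 against 9.23. Also lower were the AP-1 gene Fosl1 (7.72 against 9.55), the costimulatory gene Cd80 (6.82 against 8.65), the thin filament gene Lmod3 (8.56 against 10.17) and Sprr1a (7.61 against 9.21). The p53 target (-0.45), oxidative stress (-0.32), cytokine (-0.3), heat shock (-0.3), fetal gene (-0.26), immediate early (-0.21), sarcomere (-0.2), TCA cycle (-0.2), NF-kB (-0.18), oxidative phosphorylation (-0.17) and fatty acid oxidation (-0.15) medians lay below the random range. Members with the largest differences were Slc7a11 (10.34 against 11.64), Hspa1b (6.74 against 8.22), Myh7 (12.34 against 12.84), Ldb3 (13.0 against 13.71) and the carnitine palmitoyltransferase gene Cpt1b (12.21 against 13.27). The antigen presentation median was -0.22, but -0.09 and inside the range with values below the floor raised to it, and 0.01 with the floor at the 75th percentile. Calcium handling (-0.08), fibroblast activation (0.13) and ribosomal protein (0.09) medians did not stand apart. Of the negative control probe sets past the floor 17.7% differed by at least 2-fold, against 1.53% of genes.

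The direct comparison of cardiomyocytes gave few large differences, with 13 of 9995 genes at least 2-fold higher with Ccrl2+ than with Ccrl2- and 18 lower. With values below the floor raised to it these counts were 7 and 9. Lower with Ccrl2+ were the chemokine gene Ccl9 (10.88 against 12.39), the sulfatase gene Sulf1 (11.11 against 12.45), Col1a1 (10.07 against 11.3), Col11a1 (7.7 against 8.89) and Col3a1 (9.77 against 10.93). Higher were Igsf23 (8.38 against 7.06), the growth factor-like gene Ccn5 (7.72 against 6.34, at least 1.17), the heat shock gene Hspa1b (7.82 against 6.74) and Kcnip2 (at least 0.75), a potassium channel subunit gene. Fibroblast identity (-0.41), epicardial (-0.44), complement (-0.45), macrophage marker (-0.36), mitosis (-0.29), cholesterol synthesis (-0.23) and collagen (-0.19) medians lay below the random range. Oxidative stress (0.22), p53 target (0.17), fatty acid oxidation (0.16), TCA cycle (0.15), sarcomere (0.13) and oxidative phosphorylation (0.08) medians lay above it. Examples were C1qc (9.39 against 10.07), Plk1 (11.43 against 12.0), Lmod2 (12.66 against 11.85) and Cpt1b (13.07 against 12.21). The cytokine (0.04), NF-kB (0.07) and interferon-stimulated (-0.14) medians did not stand apart. Ccrl2 lay at 7.77 in PBS, 7.61 with Ccrl2+ and 7.45 with Ccrl2-.

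Both secretomes differed from PBS in much the same direction in cardiomyocytes. Rsad2, Ifit1 and Ccl3 were lower with each secretome, and Cenph and Slc16a3 were higher. Across 9939 genes r was 0.67 and the covariance 0.0697, against 0.501 and 0.0306 simulated for unchanged groups with a shared PBS array. At 2-fold 10 genes were higher in both, against 0.1 for independent lists, and 19 lower in both, against 0.5. Unchanged groups with a shared PBS array gave 0.47 genes shared in either direction, and the PBS array could not be split here either. That simulation gave every array the same noise, taken from the cardiomyocyte secretome arrays, the closest pair. A PBS array that deviated more by itself would also raise r and the shared counts. These values therefore cannot tell an effect of both secretomes from a deviating PBS array.

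**Figure D3:**
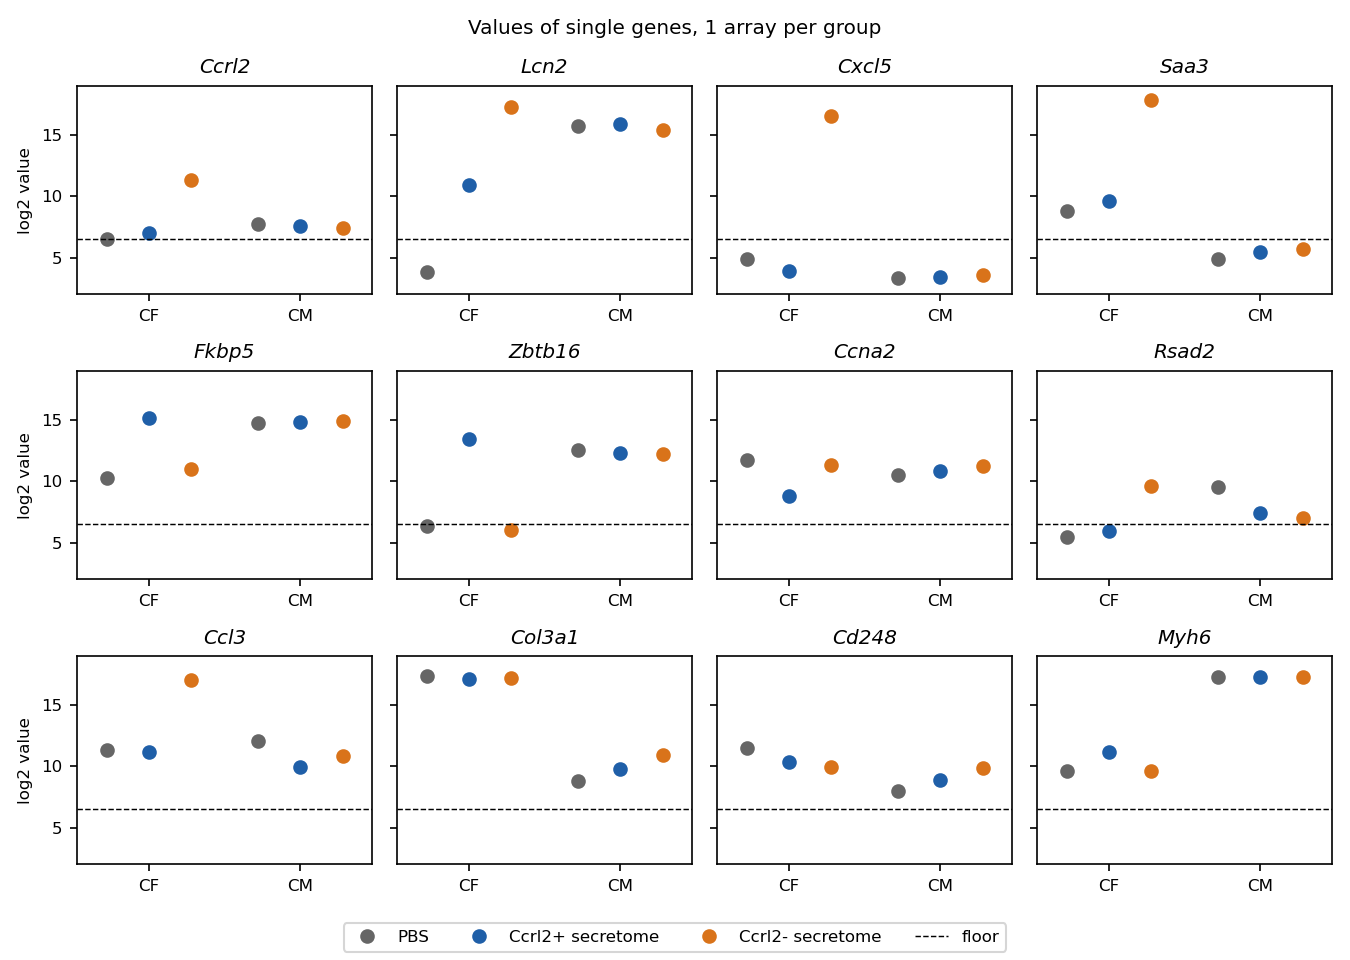
Log2 value (vertical axis) of 12 named genes on each of the 6 arrays, with PBS in grey, the Ccrl2+ secretome in blue, the Ccrl2- secretome in orange and the floor of 6.55 as a dashed line. In fibroblasts Cxcl5 stands at 16.56 in the array labelled Ccrl2- and Zbtb16 at 13.44 in the array labelled Ccrl2+, while in cardiomyocytes Rsad2 goes from 9.53 in PBS to 7.45 and 6.97, and Col3a1 from 8.78 to 9.77 and 10.93.

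Between the cell types, the differences of Ccrl2+ from Ccrl2- were not correlated across genes. Over 9482 genes Pearson's r was -0.007 and Spearman's rho 0.001. The cardiomyocyte difference was small, with 31 of 9995 genes at 2-fold and an SD of 0.274, and it served above as the estimate of noise. Such an r therefore cannot show whether an effect was shared. At 2-fold, 2 genes were lower with Ccrl2+ in both cell types, Ccl9 (13.5 against 14.64 in CF) and the macrophage gene Aif1 (6.56 against 8.73 in CF, at least 0.71 lower in CM), against 1.3 for independent lists. Col11a1 (12.24 against 10.91) and Agmo (8.35 against 5.72, at least 1.8) were higher with Ccrl2+ in CF and lower in CM (7.7 against 8.89, and 5.88 against 7.01, at least 0.46), against 1.1 for independent lists.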

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

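The results in this part were singled out because a gene list or gene went in opposite directions in fibroblasts and cardiomyocytes, or because control probes differed between arrays. None of the differences between cell types was tested, since each group had 1 array. The tests of macrophage share, exchanged labels, carried-in cardiomyocytes (both tests) and fibroblast share, and the glucocorticoid target list, were chosen after the arrays had been seen.

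With the Ccrl2+ secretome over PBS, the fibroblast and cardiomyocyte medians were -1.96 and 0.46 for mitosis, -1.26 and 0.28 for DNA replication, 0.54 and -0.37 for antigen presentation, and -0.45 and 0.12 for cholesterol synthesis. With the Ccrl2- secretome over PBS they were 5.12 and -0.3 for cytokines, 4.38 and -0.18 for NF-kB genes, 3.52 and -0.81 for interferon-stimulated genes, 3.2 and -0.22 for antigen presentation, 0.89 and -0.21 for immediate early genes, 0.53 and -0.32 for oxidative stress, and 0.21 and -0.45 for p53 targets. They were -0.86 and 0.39 for myofibroblast contractile genes, -0.62 and 0.72 for fibroblast identity, and -0.59 and 0.77 for epicardial markers, whose CF median was -0.35 and inside the random range of -0.39 to 0.22 with values below the floor raised to it. The CM antigen presentation median of -0.22 was -0.09 in the same way, inside its range of -0.21 to 0.16, and 0.01 with the floor at the 75th percentile, so its direction is not firm. For Ccrl2+ over Ccrl2- they were 0.52 and -0.2 for myofibroblast contractile genes, 0.44 and -0.41 for fibroblast identity, -1.07 and 0.11 for the unfolded protein response, -0.55 and 0.22 for oxidative stress, and -0.51 and 0.17 for p53 targets. In the same comparison Col11a1 differed by 1.33 in CF and -1.19 in CM, and Agmo by 2.63 and -1.13. The dimmer Agmo values lay below the floor, which leaves at least 1.8 and at least 0.46. The median of the 4 poly-A spike-in transcripts was 0.61 higher in the CF array of the Ccrl2+ secretome than in its PBS array, and 0.89 higher than in the CF array of the Ccrl2- secretome. For the 4 hybridisation spike-in transcripts these medians were 0.305 and 0.33.

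The cytokine, acute phase and interferon genes that were higher in the fibroblast array labelled Ccrl2- were weighed against 3 explanations. A larger share of macrophages in an unchanged state would raise macrophage markers, but their median was -0.45. The highest of Ptprc, Adgre1, Lyz2, Csf1r and Tyrobp was 1.32. Of 21 markers past the floor, 5 were at least 2-fold higher and 8 lower. Markers such as Lyz2 (12.52) were already high in PBS, where cytokine genes such as Cxcl2 lay below the floor. Macrophages in another state could therefore carry the cytokine genes with little change in markers, and the test cannot decide on that. The median over the negative controls was -0.01. The arrays had been brought to almost one distribution before deposit, which limits any such shift, and even CF over CM in PBS gave only 0.55. This value therefore cannot decide on a shift of control probes. The series title describes CCRL2 macrophages as inflammatory, while these genes stood in the array labelled Ccrl2-, so exchanged labels of the fibroblast arrays were considered: the NF-kB list differed by only -0.07 between the cardiomyocyte arrays labelled Ccrl2- and Ccrl2+, which decides nothing, and exchanged labels and a true difference between the secretomes cannot be told apart here. A contaminant such as endotoxin, a difference in medium and the question which cells carried the transcripts were not tested and stay open.

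Zbtb16, Fkbp5 and others were higher in the fibroblast array labelled Ccrl2+. Cardiomyocytes also had high values of both (14.72 for Fkbp5 and 12.56 for Zbtb16 in PBS), but the 18 sarcomere genes at least 32-fold higher in CM than CF gave a carried-in share of at most 1.56% (median 0.25%), and 97.5% of the 489 genes at least 2-fold higher over PBS needed more. Of 4 sarcomere genes closer between the cell types, Tnnt2 gave 23.4% and the others negative shares. Of the 489 genes 87.9% needed more than that too. These shares argue against carried-in cardiomyocytes in the state of the cardiomyocyte PBS array for most of the pattern. For the rest such cells stay open. Every share was taken against that array, so cardiomyocytes in another state are not covered. The other test did not decide: 45.4% lay at least 2-fold above their cardiomyocyte level, short of the majority set as its bar. Glucocorticoid receptor activity is a candidate explanation: 21 other known targets had a median of 0.92, above the random range of -0.31 to 0.16. Of these, 10 were at least 2-fold higher and 1 lower. In the Ccrl2- array the median was 0.11, at the upper edge of its range of -0.31 to 0.11 (percentile 97.3), with 7 higher and 3 lower. In cardiomyocytes with the Ccrl2+ secretome it was -0.22, below its range of -0.13 to 0.11. The list was already higher in cardiomyocytes in PBS, with a CF over CM median of -1.0 (-0.54 with values below the floor raised to it). A hormone in the medium of the fibroblast culture and an effect of the secretome on fibroblasts both stay open.

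Collagen and fibroblast genes were higher in the cardiomyocyte array labelled Ccrl2-. Of 127 other genes at least 8-fold higher in fibroblasts, 83.5% were higher there than in PBS (median 0.48), against 48.4% of genes similar in both cell types. A larger share of fibroblasts would give such a shift. The 127 genes were picked partly by a low value on the same cardiomyocyte PBS array. That by itself favours higher values on other cardiomyocyte arrays, and the 48.4% does not carry this lean. With an added share of 1.83%, 18 matrix genes lay a median of 0.13 from the expected level (quartiles -0.07 and 0.27), down from 0.68. The matrix genes thus rose little beyond what the other fibroblast-enriched genes gave. That share was fitted to those other genes on the same arrays. A program raising all fibroblast genes in cells already present would give a like result, so the test cannot tell it from added cells. In the Ccrl2+ array 73.2% of the 127 genes were higher (median 0.18), with the same lean. Whether the secretome made fibroblasts grow, raised fibroblast genes in cells already present or the culture began with more fibroblasts stays open.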

How the results depend on the processing

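Raising values below the floor to it was the only alternative chosen after the results were seen. No paired analysis was possible because each group had 1 array, and for the same reason no array was left out. A pseudocount was not varied because the values were already on the log2 scale.

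Under quantile normalization, removal of a loess trend and the mean of a gene's probe sets, every count at 2-fold stayed within 1.5 times its value. Quantile normalization could change little, since the deposited arrays already had almost one distribution. The mean of probe sets touched only the 55 symbols with several probe sets. Stability under either is therefore no strong check. The number of lists standing apart was 108 as reported and lay between 95 and 111 over the alternatives. By more than 1 SD of the matched random lists, 1 list median moved and 227 did not under quantile normalization, and likewise under the mean of probe sets. With loess 9 moved and 219 did not, with values raised to the floor 24 and 204, with no floor 56 and 172. With the floor at the 75th percentile 49 moved, 2 reversed and 151 did neither.

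Thresholds change the counts by construction. At 1.5-fold the numbers of genes higher and lower were 1148 and 1504 for Ccrl2+ over PBS in CF, 1071 and 1490 for Ccrl2- over PBS in CF, 1854 and 1951 for Ccrl2+ over Ccrl2- in CF, 218 and 326 for Ccrl2+ over PBS in CM, 465 and 462 for Ccrl2- over PBS in CM, 232 and 239 for Ccrl2+ over Ccrl2- in CM, and 2540 and 2697 for CF over CM. At 3-fold they were, in the same order, 215 and 212, 395 and 102, 346 and 512, 0 and 8, 11 and 8, 0 and 0, and 721 and 1034.

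With the floor at the 75th percentile, which counts fewer genes by construction, they were 228 and 284, 363 and 260, 463 and 553, 1 and 23, 22 and 22, 0 and 4, and 840 and 980. The correlations across genes were then -0.041 between CF and CM, 0.243 between the secretomes in CF and 0.687 in CM. The calcium handling median for Ccrl2+ over PBS in CF went from 0.24 to -0.29, and the antigen presentation median for Ccrl2- over PBS in CM from -0.22 to 0.01. The cause was not tested.

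With no floor, which adds genes near background, the CM counts were 54 and 108 for Ccrl2+ over PBS, 141 and 131 for Ccrl2- over PBS, and 30 and 53 for Ccrl2+ over Ccrl2-, with a correlation of 0.613. With values raised to the floor, which shrinks differences by construction, the counts for Ccrl2+ over Ccrl2- in CM were 7 and 9 and the correlation in CM 0.663. Signal over background limits the dimmer genes: the 95th percentile of the negative controls was 10.51, above many values named in the report.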

Other observations

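Interferon-induced and fibroblast genes lay on opposite sides in the cell types when the Ccrl2- secretome was set against PBS. Among 9451 genes past the floor in both, 16 were at least 2-fold higher in fibroblasts and lower in cardiomyocytes, against 2.61 for independent lists, and these cell types share no PBS array. They included Ifit1, Ifit3, Oasl2, Rsad2, Usp18, Ccl3, Fosl1 and Slc7a11. In the opposite class, 17 genes were lower in fibroblasts and higher in cardiomyocytes, against 3.12, among them Cd248, Mylk, Itga8 and Fgf2. Higher in both were 5 genes, against 3.76, including Slc16a3 and, chosen after its values were seen, the hyaluronan synthase gene Has2. Lower in both were 7, against 2.17, including Tlr7, Tmem119 and Ccn5. Across these genes r was -0.091.

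With the Ccrl2+ secretome 9 genes were higher in fibroblasts and lower in cardiomyocytes, against 2.32 for independent lists. They were C1qc, Ccl6, Ccl9 and, chosen after their values were seen, Ifi207, Ms4a6b, Ms4a6d, Pirb, Vsig4 and Wfdc17. The fixed macrophage marker list, which includes C1qc, had a median of -0.87 in the same cardiomyocyte comparison, with 8 of 20 genes at least 2-fold lower, and of 0.14 in fibroblasts, inside the random range. The genes higher in both were Fmo2, Ndufa4l2 and, chosen after their values were seen, Deptor and Dpep1, 4 against 0.6. Lower in both were 5, against 2.96, and lower in fibroblasts but higher in cardiomyocytes 3, against 0.77, namely Ska3, Slc16a3 and, chosen after its values were seen, Depdc1a. Across 9448 genes r was -0.023. These overlaps were counted after the results were seen, and none was tested.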
